A study of Mus musculus with 8 samples.

How the data were processed

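Liver RNA of 8 mouse libraries (5 alcohol gavage, 3 saline gavage) was extracted with TRIzol and sequenced on an Illumina HiSeq X10, per the labels' protocols. The submitters' processing notes list CASAVA 1.8, Bowtie, TopHat2 and the GRCm38 genome build, with no role or order, and their roles are not given in the sources used here. The counting program, the annotation release, strand handling and any filter are not given in the sources used here. The authors deposited a table of estimated counts per gene, not normalised, with 1 column per library and 22525 rows, of which 21937 carry Ensembl identifiers and 588 are assembled loci with their own identifiers. Between 5.73% and 6.58% of the values of a library were not whole. Values were rounded to whole counts before testing. For 27 symbols in the deposited table that had turned into calendar dates, the name was taken by identifier from GENCODE M21, which is on the same build and also gave coordinates, transcript GC content and length. All 8 value columns were used. Their group was read from the prefix of the name (A for alcohol, NC for the control), with 5 and 3 columns for 5 and 3 samples. No label states this reading, and all directions rest on it. The names do not show the replicate number of the labels, so the number pairs no libraries.

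Before the data were examined, the groups, the tests, 39 gene lists and the rule for named genes were fixed. Genes were kept by filterByExpr on the group, scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit with robust = TRUE, glmQLFTest; edgeR 4.0.16, limma 3.58.1, R 4.3.3), with the group as the only term and Benjamini-Hochberg adjustment over the genes tested. A gene passed at an adjusted p under 0.05. Log2 fold changes are alcohol minus saline, their standard errors are the unshrunken coefficient divided by the square root of F, and CPM are counts relative to the TMM-scaled library total. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), with camera with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. Library measures were compared with exact permutation tests over all 56 divisions into 5 and 3, two-sided.

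Named were the 10 genes with the largest increase and the 10 with the largest decrease among those that passed, whose groups did not overlap, with a mean of at least 50 counts and no predicted, clone or pseudogene name; Adh1, Aldh2, Cyp2e1 and Cat; and of each list the 4 members with the smallest p. Some genes that the rule names are not reported here. Genes with near-identical copies were treated as uncertain. Other genes that the text names as members of a list by their call or as exceptions are identified there by that role. A group with 0 counts allows up to 3 counts.

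After the data were examined, a GC correction was added. For each library, a lowess curve (span 0.3) of the deviation of log2 CPM (prior count 1) from the mean of the group means over transcript GC content was removed as an offset in the same model. Genes without a GC value were left out, which kept 12133 of the 12492 tested genes. Because the trend parts the groups completely, the correction also removes any true response that follows GC content. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among 12350 tested, the test recovered 84% and 95% with 16 false calls, 8.21% of all calls. With the same straight GC trend added to every alcohol library and no correction, 6035 genes were called falsely among 12282, 97.1% of all calls. With the correction, 13 false calls were made among 11941, 6.77% of all calls, and 85.9% and 96.9% of changed genes were recovered. The observed trends were curved and differed between libraries. A far larger share of genes was called in the data (66.4%, or 51.9% after GC correction) than was changed in the simulation. These counts therefore need not hold for the data.

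Alternatives fixed beforehand were RLE size factors, no filter beyond 1 count in total, a mean of at least 50 counts, leaving out each library in turn, DESeq2 1.42.0 (Wald test), limma-voom, robust = FALSE, a 2-fold threshold and an adjusted p under 0.01. GC correction, GC and length correction, leaving out the assembled loci, GC correction with a library left out, and counts of list members with a library left out were added later. Library totals ran from 17171303 to 23545734 counts, so precision is lowest for genes of a few counts. Ratios of genes with 1 to 3 counts in a group are given with exact 95% counting intervals.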

Results

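Liver RNA was sequenced from C57/B6 mice of 2 groups, 5 libraries after alcohol gavage and 3 after saline gavage. Mice of the alcohol group received a 20% alcohol solution each day over 2 weeks, at 15 µL per g. The titles and the treatment protocol call the control saline, and the treatment label calls it water. The comparison asked which liver genes differ between the groups. Totals ran from 17171303 to 23545734 estimated counts per library and averaged 20647500 ± 1451890 (SD, n = 5) after alcohol and 20915900 ± 3330240 (SD, n = 3) after saline. Libraries named A4 to A8 in the deposited table were read as alcohol and NC3 to NC5 as saline, from the names and the number of columns. Nothing states that each library came from a separate mouse, so the p-values measure the spread between these libraries, which may be technical. Counts also followed transcript GC content differently in the 2 groups, and values after a GC correction are given where the correction ended a call, turned a direction or moved a value most.

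Metallothioneins, acute phase proteins and neutrophil granule proteins were among the largest named increases in the alcohol livers, and major urinary proteins and the xenobiotic-metabolising enzyme Cyp1a1 among the largest named decreases. Mt2, a metal-binding protein (chromosome 8, 94172664 to 94173568, GRCm38 as for all positions), averaged 925 ± 532 normalised CPM (SD, n = 5) after alcohol and 0.434 ± 0.396 (SD, n = 3) after saline. Its log2 fold change was 10.97 ± 1.25 (SE, adjusted p = 2.3e-04), and 11.59 without saline library NC5. Mt1 rose by 8.52 ± 0.99 on the log2 scale, Lcn2 (chromosome 2, 32384633 to 32388252), an iron-sequestering acute phase protein, by 7.55 ± 1.10, and Saa1 and Saa2, serum amyloid A proteins of near-identical sequence whose separate values are uncertain, by 7.50 ± 1.51 and 9.07 ± 2.07. The myeloid granule enzyme Prtn3 was at 16.3 ± 7.03 CPM after alcohol and 0.0648 ± 0.112 after saline, where all 4 counts were in NC5. Its log2 fold change of 7.82 became 7.20 after GC correction and 7.18 without NC4, and without NC5 it was at least 214-fold higher, with the 0 saline counts set at a floor of 3 over the group. Mpo, a further granule enzyme, had 469 counts after alcohol and 3 after saline, a ratio of 89.9 with a 95% counting interval of 30.6 to 437 (168 without NC4, with 1 saline count and an interval of 30.0 to 6642). Ciart, a repressor of the circadian clock, had 974 and 3 counts, a ratio of 187 with an interval of 63.7 to 907 (370 without NC5, with 1 saline count and an interval of 66.2 to 14610). The intervals are exact (Clopper-Pearson), and they and the floor cover counting error only. The nicotinamide methyltransferase Nnmt rose by 6.5 ± 1.32. These 9 genes had adjusted p-values from 1.7e-04 to 0.00754.

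Cyp1a1 (chromosome 9, 57687928 to 57703824) was at 1.14 ± 0.254 CPM after alcohol and 575 ± 489 after saline, a log2 fold change of -8.97 ± 1.21 (adjusted p = 6.2e-04), although saline library NC5 held 22.9 CPM against 751 and 951 in the other 2. Of the major urinary proteins, liver-secreted pheromone carriers encoded by near-identical genes whose separate counts are uncertain, 7 were among the 10 named decreases. Mup7 (chromosome 4, 60066469 to 60070475) averaged 90.2 ± 103 CPM after alcohol and 6701 ± 1865 after saline, a log2 fold change of -6.21 ± 1.07 (adjusted p = 0.00202; -5.18 after GC correction, -7.16 without alcohol library A7). Mup21 fell by 6.55 on the log2 scale, and the change was -5.02 after GC correction and -7.33 without A7. Values for Mup20, Mup14, Mup17, Mup8 and Mup12 were -4.91, -4.81, -4.69, -5.94 and -6.01, or -3.52, -3.74, -3.59, -4.87 and -4.86 after GC correction, with Mup12 at -7.14 without A7. Adjusted p-values of these 7 genes ran from 6.3e-08 to 0.00690. Cyp2c55, of the Cyp2c family of near-identical genes, was at -5.24 (-4.10 after GC correction, -6.81 without A8, -4.65 without NC5). Hist2h2aa2 had 0 counts in all 5 alcohol libraries, but 100% of its 50-nt words recur in Hist2h2aa1, so no fold is given. Summed, the 2 histone genes rose by 0.60 ± 0.10 (SE, adjusted p = 2.3e-04) without GC correction, which was not run on the sum.

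**Figure D1:**
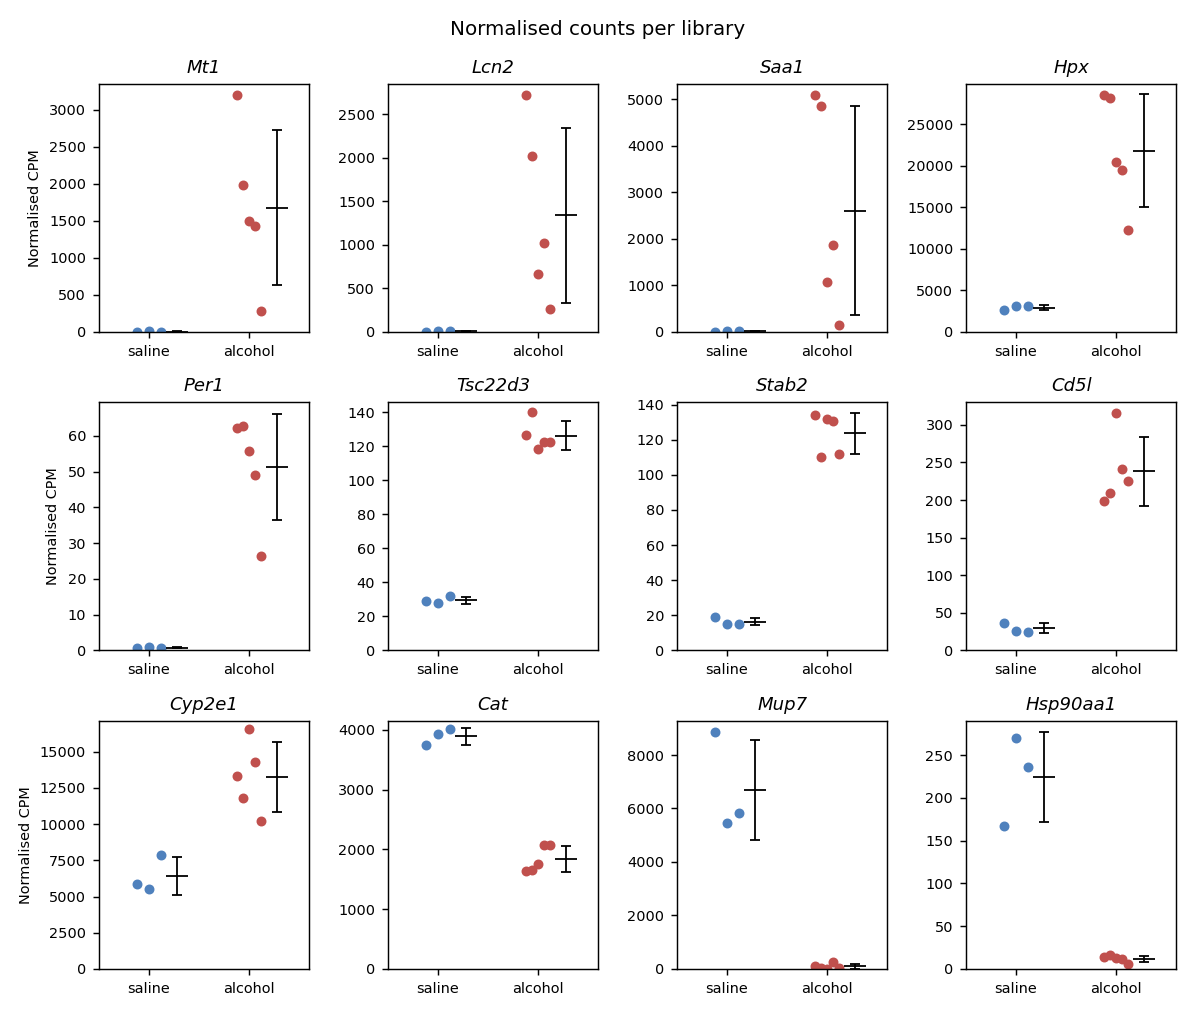
Normalised CPM (y axis, linear, from 0) of 12 genes in the 3 saline (blue) and 5 alcohol (red) libraries, 1 point per library. Black bars give the group mean ± SD. Cyp2e1 averaged 13253 ± 2407 CPM after alcohol and 6425 ± 1288 after saline.

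Of the enzymes that oxidise ethanol and acetaldehyde, Cyp2e1, the ethanol-inducible cytochrome P450 (chromosome 7, 140763739 to 140774987), rose to 2.06 times the saline level. Its log2 fold change was 1.04 ± 0.19 (SE, adjusted p = 4.0e-04) and 1.38 ± 0.19 after GC correction. Cat, the peroxisomal catalase, fell from 3893 ± 141 to 1837 ± 218 CPM (-1.08 ± 0.12, adjusted p = 1.3e-05), and the retinal and acetaldehyde dehydrogenase Aldh1a1 was at -1.19 ± 0.12 (adjusted p = 4.4e-06). Adh1, the main hepatic alcohol dehydrogenase, was at 1638 ± 342 CPM after alcohol and 1884 ± 105 after saline (-0.20 ± 0.16, adjusted p = 0.289). Aldh2, the mitochondrial acetaldehyde dehydrogenase, passed the threshold at 0.36 ± 0.11 (adjusted p = 0.0155), but its adjusted p was 0.0617 without NC4 and 0.0535 without NC5, and its change was -0.09 ± 0.11 after GC correction (adjusted p = 0.494). In the list of 12 genes 3 rose and 5 fell, the same 8 when adjusted over the list alone, and the list did not shift against other genes (camera, adjusted p = 0.685). After GC correction 2 rose and 5 fell. Of all 12492 tested genes 66.4% passed, 4124 higher and 4173 lower, and 51.9% of those tested passed after GC correction. Counts of list members here and below stand beside those shares.

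Acute phase genes and genes known to respond to glucocorticoids both rose. Lcn2 is in both lists, and Per1 is also in the circadian clock list. Of 24 acute phase genes 19 rose and 1, Cp, fell (20 passed when adjusted over the list alone; 23 rose and 0 fell after GC correction), with a median log2 fold change of 2.44 (camera, adjusted p = 2.1e-04; adjusted p = 0.733 with an estimated correlation). Hpx, the haem-binding hemopexin (chromosome 7, 105591613 to 105600137), averaged 21780 ± 6795 CPM after alcohol and 2928 ± 270.5 after saline (2.90 ± 0.28, adjusted p = 4.6e-06). Lbp, which binds bacterial lipopolysaccharide, rose by 3.16 ± 0.33, and the inter-alpha-trypsin inhibitor chains Itih3 and Itih4 by 3.0 ± 0.37 and 2.80 ± 0.33. The copper carrier Cp, chosen after its values were seen, was at -0.65 (adjusted p = 0.00988) and, after GC correction, at 0.51 (adjusted p = 0.0248). Of 13 glucocorticoid-responsive genes 12 rose (the same number adjusted over the list alone and after GC correction, where 1 fell without NC4; median 2.41, camera adjusted p = 1.6e-06; adjusted p = 0.445 with an estimated correlation), and Dusp1, chosen after its values were seen, did not pass (-0.84 ± 0.63, adjusted p = 0.273). Tsc22d3, a leucine zipper protein induced by glucocorticoids (chromosome X, 140539528 to 140600659), rose by 2.10 ± 0.10 (adjusted p = 4.8e-08). The period gene Per1 (chromosome 11, 69095217 to 69109960) rose by 6.01 ± 0.41 (5.40 ± 0.46 after GC correction), the transcription factor Zbtb16 by 3.68 ± 0.35, and Pck1, the rate-limiting enzyme of gluconeogenesis, by 2.41 ± 0.18. Acute phase levels varied among the alcohol libraries: Saa1 ran from 138 CPM in A8 to 5077 in A4.

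Markers of macrophages, neutrophils and sinusoidal endothelium were higher in the alcohol livers. All 12 Kupffer cell and macrophage markers rose, with a median log2 fold change of 1.77 (camera, adjusted p = 4.3e-09; adjusted p = 0.445 with an estimated correlation). Cd5l, a protein secreted by macrophages, averaged 238 ± 46.1 CPM after alcohol and 29.2 ± 6.72 after saline (3.03 ± 0.20, adjusted p = 3.9e-07), and the complement subunit C1qa rose by 2.05 ± 0.11 (1.42 ± 0.10 after GC correction). All 11 sinusoidal endothelial markers rose (median 1.5, camera adjusted p = 7.3e-09; adjusted p = 0.445 with an estimated correlation). Stab2, a scavenger receptor of these cells, rose by 2.92 ± 0.13 (adjusted p = 3.9e-08) and the lectin Clec4g by 1.41 ± 0.09. All 9 tested neutrophil markers rose (median 3.87, camera adjusted p = 0.0120; adjusted p = 0.722 with an estimated correlation, and 0.197 with genes under a mean of 50 counts left out). Their levels were low, with S100a9, a calcium-binding neutrophil protein, at 5.60 ± 2.88 CPM after alcohol and 0.440 ± 0.232 after saline (3.63 ± 0.69, 4.22 ± 0.67 after GC correction). As many passed in each of the 3 lists when adjusted over the list alone and after GC correction. Among cytokines, chemokines and NF-kB targets 9 of 14 rose and 1, Cxcl9, fell (10 when adjusted over the list alone, 10 higher and 0 lower after GC correction with 1 lower without A8; camera, adjusted p = 0.0419, or 0.0907 with genes under a mean of 50 counts left out; adjusted p = 0.538 with an estimated correlation). The endothelial adhesion molecule Icam1 rose by 2.13 ± 0.22, while the chemokine Cxcl9, at -1.42 ± 0.25, no longer passed after GC correction (-0.49 ± 0.28, adjusted p = 0.168). The cell type markers moved apart: of 6 cholangiocyte markers 0 rose and 3 fell (3 when adjusted over the list alone; camera, adjusted p = 0.449), with the secreted phosphoprotein Spp1 at -1.67 ± 0.12 (-0.75 ± 0.13 after GC correction). The keratin Krt19, at -1.83 ± 0.66, lost its call without A4, A5, A6, A7 or NC4, with limma-voom and with no filter on low counts. Without NC4, which held 9.28 CPM of Krt19 against 1.11 and 2.19 in the other saline libraries, it was at -0.48, and the list median went from -0.84 to -0.29. After GC correction 4 of the list fell, 3 without NC4.

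Genes of cholesterol synthesis and genes more highly expressed in male than in female mouse liver were lower after alcohol. In the cholesterol list 16 of 24 genes fell and 2 rose (all 18 also when adjusted over the list alone), with a median of -1.07 (camera, adjusted p = 0.0451; adjusted p = 0.889 with an estimated correlation). That list call was lost, with adjusted p-values from 0.0515 to 0.0811, on leaving out A4, A5, A6, A7, NC3 or NC4 (10 fell without NC3, and 1 rose without NC5), and held after GC correction (18 fell and 1 rose, adjusted p = 2.0e-04, or adjusted p = 0.673 with an estimated correlation). Hmgcs1, which forms HMG-CoA, averaged 26.2 ± 10.5 CPM after alcohol and 172 ± 45.0 after saline (-2.71 ± 0.31, adjusted p = 1.2e-04; -1.75 ± 0.36 after GC correction). Of 16 male-biased genes 14 fell (14 when adjusted over the list alone, 15 after GC correction; median -2.71, camera adjusted p = 2.9e-04; adjusted p = 0.722 with an estimated correlation). Beside Mup20 these included the complement component C6 (-1.76 ± 0.22) and Cyp7b1, an oxysterol hydroxylase (-2.41 ± 0.19; -1.36 ± 0.21 after GC correction). Of 10 female-biased genes 3 rose (1 without NC3 or NC5; 1 when adjusted over the list alone, 3 after GC correction and then 1 without A4) and the list did not pass (camera, adjusted p = 0.435). Of these, the calls of Cyp2b9 (2.20 ± 0.69) and Cux2 (4.60 ± 1.56, 3.21 without alcohol library A6) were lost on leaving out A8, NC3, NC4 or NC5. The call of Cux2 was also lost after GC correction (4.14 ± 1.64, adjusted p = 0.0716), with limma-voom (3.67, adjusted p = 0.0650) and with no filter on low counts (adjusted p = 0.0526).

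Genes of fatty acid and triglyceride synthesis stood apart in alcohol library A8, where 15 of 20 lay at least 1 log2 unit above the mean of the other 4 alcohol libraries. Over all libraries 4 of 20 genes rose and 3 fell (6 when adjusted over the list alone), with no shift of the list (median -0.38, camera adjusted p = 0.990). After GC correction 2 rose and 4 fell (median -0.79, adjusted p = 0.334), or 2 and 14 without A8 (median -1.45). Without A8 and without that correction, 14 of 19 tested genes fell and 3 rose (median -1.25, camera adjusted p = 2.9e-04; adjusted p = 0.439 with an estimated correlation). A8 was singled out by its values for these same genes, so the values without it are not an independent test of the list. Lpin1, the phosphatidate phosphatase lipin, rose by 2.28 ± 0.49 (adjusted p = 0.00491), and Mlxipl, a carbohydrate-responsive transcription factor, was lower at -0.96 ± 0.27 (adjusted p = 0.0140; -1.25 ± 0.08 without A8, and -1.59 with GC and length correction). Fasn, Acly and Elovl6, enzymes of fatty acid synthesis and elongation, were chosen after their values were seen. Fasn, fatty acid synthase, ranged from 96.7 to 207 CPM in A4 to A7 and was at 2645 in A8 and 847 ± 68.3 (SD, n = 3) after saline. Acly ranged from 92.5 to 114 CPM in A4 to A7, against 907 in A8 and 339 ± 26.6 after saline. Elovl6 ranged from 3.30 to 5.39 CPM in A4 to A7, against 36.3 in A8 and 87.8 ± 1.25 after saline.

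**Figure D2:**
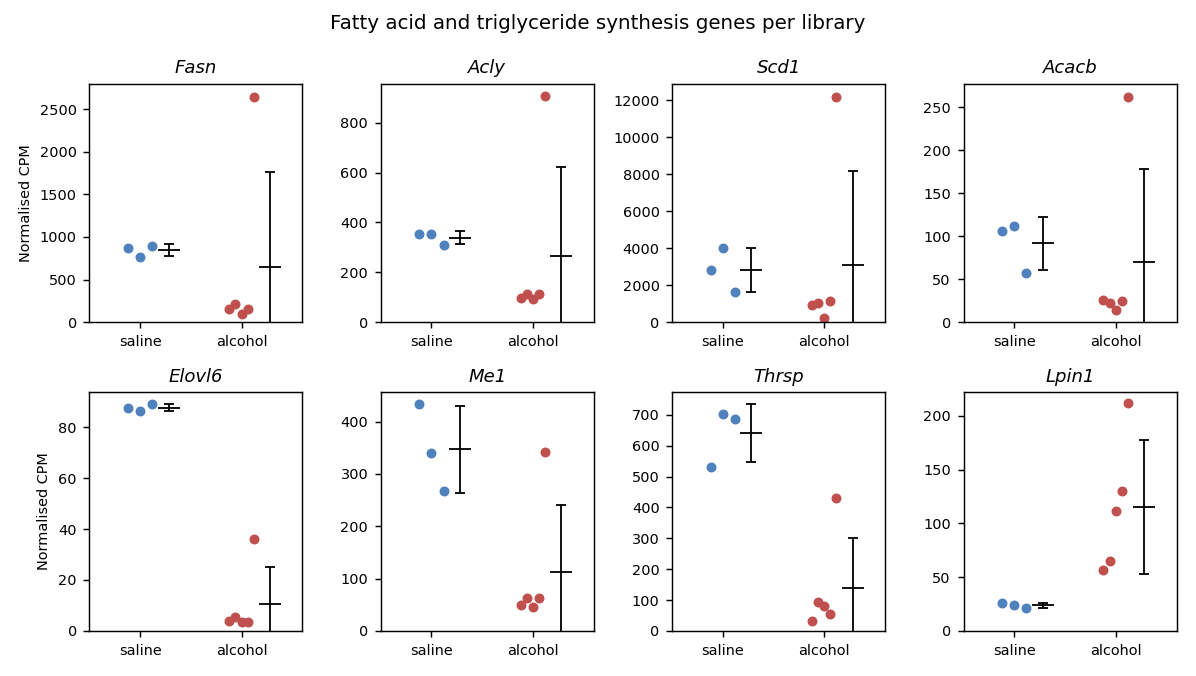
Normalised CPM (y axis, linear, from 0) of 8 genes of fatty acid and triglyceride synthesis in the 3 saline (blue) and 5 alcohol (red) libraries, with the group mean ± SD as black bars that end at 0 where the SD exceeds the mean. The alcohol point far above the other 4 in the Fasn panel is A8, at 2645 CPM.

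Of drug-metabolising enzymes, Cyp1a2, a P450 of the same locus as Cyp1a1, fell from 5347 ± 1854 to 625 ± 151 CPM (-3.10 ± 0.26, adjusted p = 3.5e-06). The list of 5 aryl hydrocarbon receptor targets had 4 lower genes (4 when adjusted over the list alone), but 2 lower and 1 higher (0 without A6, NC3 or NC5) after GC correction, where Cyp1b1 no longer passed (-0.92 ± 0.44, adjusted p = 0.0936) and Tiparp turned from -1.27 to 0.12 (adjusted p = 0.670). The list passed only without NC5 (camera, adjusted p = 6.0e-06, against 0.208 with it), among the single libraries left out. With an estimated correlation and all libraries its adjusted p was 0.722. The steroid hydroxylase Cyp3a11, of a family with near-identical members, was lower at -2.37 ± 0.23 (-1.07 ± 0.23 after GC correction), whereas the calls of Cyp3a25 (-1.47 ± 0.16) and Cyp2c29 (-1.11 ± 0.16) ended there (-0.07 ± 0.14 and -0.23 ± 0.18). In the heat shock list 5 of 10 genes fell and 0 rose (5 when adjusted over the list alone, 3 without NC5, and 5 after GC correction with 9 without NC3; camera, adjusted p = 0.208, 0.00515 after GC correction and 0.0192 without NC3). With an estimated correlation its adjusted p was 0.889, and 0.665 after GC correction. The cytosolic chaperone Hsp90aa1 (chromosome 12, 110690605 to 110702728) averaged 11.9 ± 3.61 CPM after alcohol and 224 ± 52.7 after saline (-4.23 ± 0.28, adjusted p = 3.7e-06; -3.42 ± 0.25 after GC correction).

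All 13 mitochondrially encoded protein genes were lower after alcohol (median -2.17, camera adjusted p = 4.3e-11; adjusted p = 0.445 with an estimated correlation; 13 when adjusted over the list alone). They took 2.52 ± 0.109% of counts (SD, n = 5) after alcohol and 9.31 ± 0.748% (SD, n = 3) after saline (exact permutation test, two-sided p = 0.0179, the smallest the 56 splits allow). After GC correction 3 were lower and 1 higher (5 lower without A8 or NC3), the median was -0.22 and the list no longer passed (adjusted p = 0.702). mt-Nd4, a subunit of respiratory complex I, was at -2.88 ± 0.15 and -0.68 ± 0.13 before and after the correction.

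Across all genes, 12492 were tested and 8297 passed an adjusted p of 0.05, with 4124 higher and 4173 lower after alcohol (edgeR quasi-likelihood test). At 2-fold or more, 1388 were higher and 2213 lower. The change followed transcript GC content: Spearman's rho between GC content and log2 fold change was 0.656 across 12133 genes, which are not independent replicates. Among the 1215 genes with the lowest GC content the median log2 fold change was -1.48 and 88.2% of genes were called lower, and among the 1213 with the highest it was 0.65 and 67.9% were called higher. For each library, a slope over 10 points of GC content was fitted to the deviation of log2 CPM from the mean of the group means. It was 0.551 ± 0.109 (SD, n = 5) after alcohol and -0.551 ± 0.0358 (SD, n = 3) after saline, with no overlap (exact permutation p = 0.0179, two-sided). The equal and opposite group means follow from that centring, so only their difference of 1.10 is informative. With each library's GC trend removed, 6300 of 12133 genes passed, of which 4344 had also passed before in the same direction (2197 higher and 2147 lower), and 485 had passed in the opposite direction. Gclm, a glutamate-cysteine ligase subunit, was 1 of these (-0.59 ± 0.09 before and 0.52 ± 0.09 after), as was the fatty acid carrier Fabp4 (-0.61 and 0.81). Correlations of log2 CPM were 0.970 to 0.987 within the alcohol group, 0.983 to 0.985 within the saline group and 0.882 to 0.899 between groups. The first principal component took 76.2% of the variance and parted the groups, and the second took 6.99% and set A8 apart from the other 7 libraries. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom at least 21.7).

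**Figure D3:**
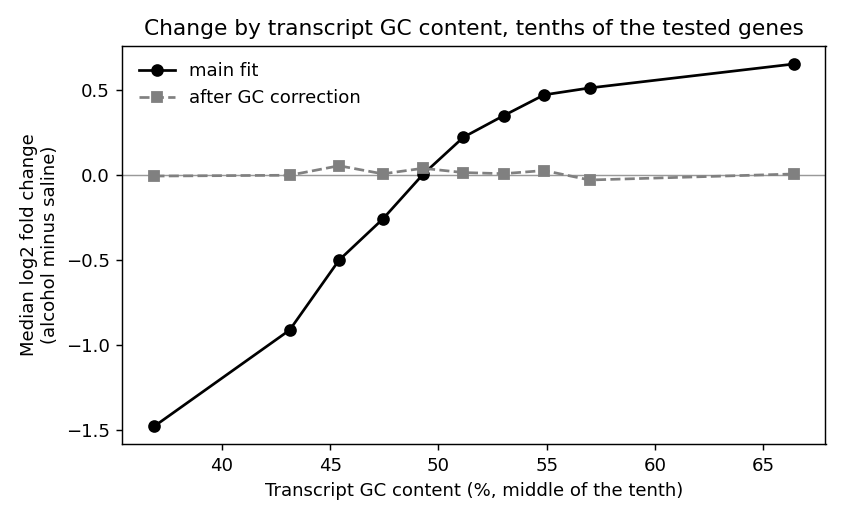
Median log2 fold change (alcohol minus saline, y axis) in 10 groups of tested genes of nearly equal size ordered by transcript GC content (x axis, percent), before (circles) and after (squares) the GC correction. The median went from -1.48 at the lowest GC content to 0.65 at the highest before the correction.

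Of the 36 gene lists with at least 3 tested members, 9 passed (camera, 6 higher and 3 lower), 0 with an estimated correlation and 20 with fry. After GC correction 10 passed, 8 of them in the same direction as before, and 0 with an estimated correlation (lowest adjusted p = 0.200). Of the 56 divisions of the 8 libraries into 5 and 3, 43, the real one included, gave at least 9 passing lists.

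**Figure D4:**
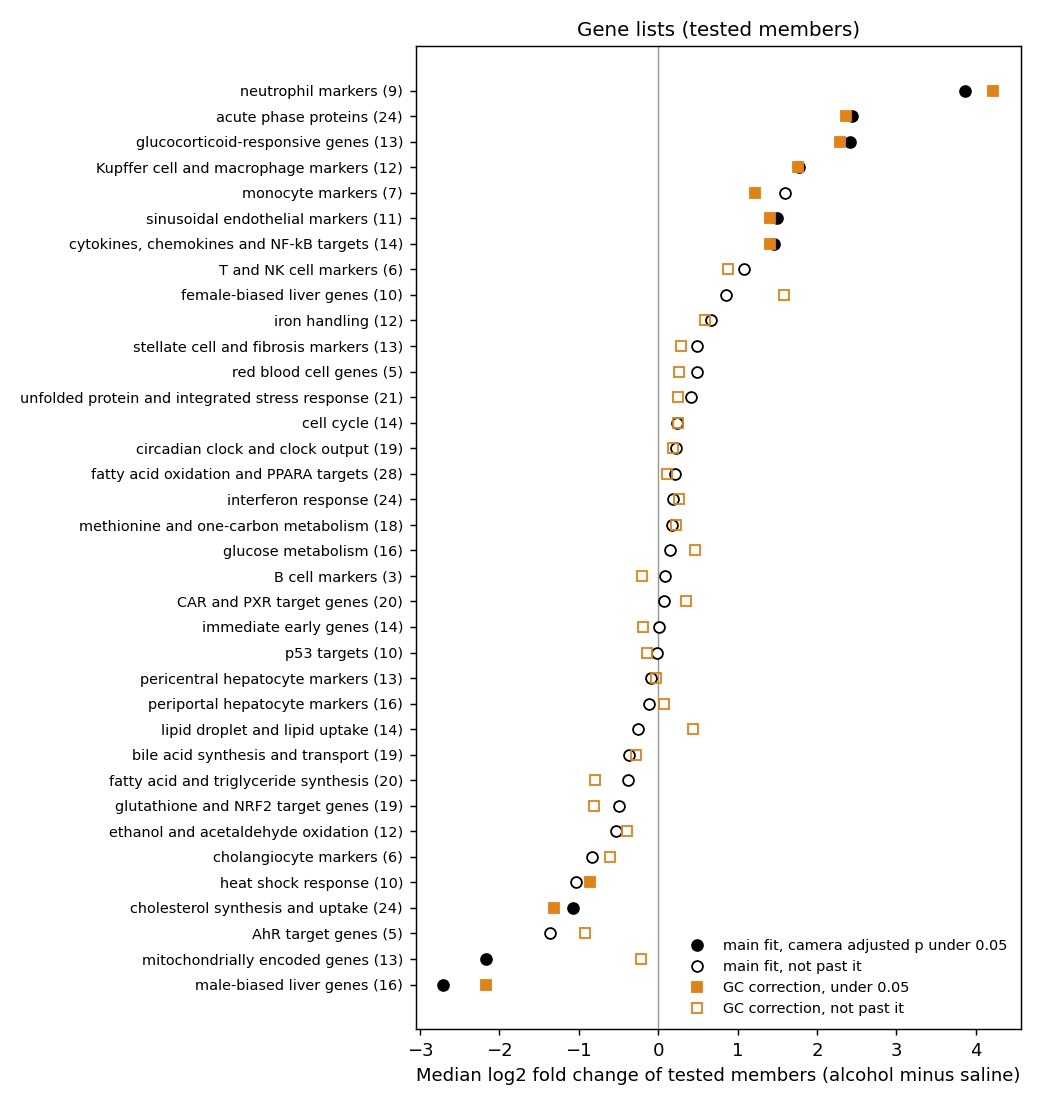
Median log2 fold change (x axis, alcohol minus saline) of the tested members of 36 gene lists, with the number tested in parentheses. Circles show the values without and squares those with GC correction, and filled symbols mark a camera adjusted p under 0.05. The neutrophil markers have the highest median (3.87) and the male-biased genes the lowest (-2.71).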

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

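The tests weighed here were chosen after the results were seen, except the counts of other divisions of the libraries. For the 2 tests on library A8 only the bounds were set before the values they measure were seen, and A8 had by then been seen to stand apart. The values set apart here come from a Dixon test in the 5 alcohol libraries (ratio above 0.71) over 200 measures, of which 9 stood out, 5 of them in A8 and 3 in A6. Chance sets apart about 1 in 20 independent measures, and 9 is no more than that. The measures are correlated, however, and most are genes named for small p-values between the groups. The count therefore cannot tell whether the departures of A8 or A6 are chance.

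The mean log2 CPM of the fatty acid and triglyceride synthesis list was 7.99 in A8 and 5.66 to 5.94 in the other 4 alcohol libraries, and Mlxipl was at 126.56 CPM in A8 and 57.1 to 61.0 in the others. Of 20 members, 15 were at least 1 log2 unit above the mean of the other 4. A GC bias of that library was tested as the cause: the median difference was 2.17 without correction. It was 2.06 with the GC trend subtracted again from values already corrected for it. Removing more of the trend than the GC correction used elsewhere thus left most of the difference, which argues against a GC bias. A saline library under an alcohol label was tested with 8411 genes called without A8, of which 88.4% lay nearer to the alcohol mean, under the 90% set before that value was seen as the bound against it. Correlations of A8 in log2 CPM without GC correction, weighed because that bound was missed, were at least 0.970 with each other alcohol library. They were at most 0.894 with any saline library, which argues against a swap. These correlations include the GC trend, which itself follows the groups. The feeding state of the mouse stays open as an untested biological explanation.

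The shift with GC content between the groups was broad: a curve over GC content took 38.7% of the variance in log2 fold change across 12133 genes. A bias of library preparation or sequencing may have produced it: a curve fitted to nuclear genes only also placed the 13 mitochondrially encoded genes, which have GC contents of 31.9 to 41.1%, at a median distance of -0.22 log2 units (SD 0.68) while their median change was -2.17. A difference in depth is argued against, because the saline libraries of lowest and highest total differed in GC slope by 0.0651 and the groups by 1.10. A response to the gavage that follows GC content cannot be told apart from a technical batch, because no label gives a batch and a gap of 0.954 parts the slopes of the groups. Assembled loci also took 0.373 ± 0.0270% of counts (SD, n = 5) after alcohol and 1.13 ± 0.114% (SD, n = 3) after saline. Of the entries of the gene Nnt, 1 was at most 0.1567 CPM in A4, A5, A7 and A8, 32.43 in A6 and at least 53.81 in saline libraries. The sum of the Nnt entries ran from 108.3 to 136.5 CPM over all libraries. Whether a batch caused these differences was not tested. The 8297 genes called in the real division were the highest count of the 56 divisions of the libraries, reached by 1 of them, and the highest of the others was 0. Every other division mixes alcohol and saline libraries, which widens the spread within its groups, so low counts there follow from the parting of the groups. Chance division is argued against only as far as 1 of 56 divisions allows, and a batch that follows the groups cannot be excluded.

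Macrophage, neutrophil and endothelial markers rose together. A GC bias as the whole cause is argued against, since the lowest of the 3 list medians was still 1.41 after GC correction. A lower share of hepatocyte RNA as the whole cause would raise markers of every other cell type alike. Cholangiocyte markers (mean corrected log2 fold change -0.99, 6 genes) instead lay below macrophage markers (1.83, 12 genes) by 2.82, and by 2.42 without NC4, where their mean was -0.66 (exact permutation test across genes, which are not independent, two-sided p = 5.4e-05 in both cases, the smallest the 18564 arrangements allow). That p-value measures the spread between genes, not between mice. Cholangiocytes were the only cell type compared, so a lower hepatocyte share as part of the cause is not excluded. More of these cells, higher expression within them and a difference in tissue handling stay open and were not tested.

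For the number of gene lists past the threshold, 43 of the 56 divisions gave at least the 9 of the real one and the highest of the others gave 19, so chance division cannot be excluded for that number.

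Per1 was at 26.48 CPM in A8 and 49.1 to 62.8 in the other alcohol libraries. Abcb11, the bile salt export pump, was at 410.72 CPM in A8 and 278 to 297 in the others. Mcm3, a replication helicase subunit, was at 11.64 CPM in A8 and 4.54 to 5.76 in the others. Fbp1, of gluconeogenesis, was at 1202.9 CPM in A5 and 1293 to 1304 in the others. C1qa was at 112.25 CPM in A6 and 96.6 to 99.2 in the others, and the mean log2 CPM of the macrophage list was 5.70 in A6 and 5.12 to 5.28 in the others. A6 also had the lowest total of the alcohol libraries, 18130252 counts against 20769178 to 21647367.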

How the results depend on the processing

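GC correction, GC and length correction, the removal of assembled loci, GC correction with a library left out, and list member counts with a library left out were chosen after seeing the data, and the other alternatives beforehand. Of the alternative values of the 159 named genes, 2556 kept their direction and their side of the threshold, 89 lost the call, 12 gained it and 25 changed sign, and of those of the 36 lists 18 lost the call, 19 gained it and 34 changed the sign of the median. The 8297 genes called became 8277 with RLE size factors, 8503 with no filter, 6992 at a mean count of at least 50, 8330 with robust estimation off, 8329 with DESeq2 (16 genes with no adjusted p), 8303 with limma-voom, 6718 at an adjusted p under 0.01, 8050 without assembled loci, 6300 with GC correction and 6154 with GC and length correction. Leaving out each library in turn gave 7460 to 8427 genes. Asking for at least 2-fold gave 3601 genes, 1388 higher and 2213 lower, by its own construction. With GC correction, 5344 genes (2686 higher, 2658 lower) were called without NC4, 5288 (2688 higher, 2600 lower) without NC5, and 2761 lower without NC3, and fewer saline libraries were then tested. The 9 lists became 0 with an estimated correlation in camera and 20 with fry, which asks another question, and 8 to 10 on leaving out a library. The signs of the following values changed, and the cause was not tested beyond the GC trend itself. With no filter the list medians of CAR and PXR targets and B cell markers were -0.0891 and -0.66, at a mean count of at least 50 those of immediate early genes and the cell cycle were -0.54 and -0.38, with limma-voom Sox9 was at -0.16, and without assembled loci immediate early genes were at -1.8e-04. With GC correction Aldh2 was at -0.0919, Tiparp 0.12, Gclm 0.52, Klf6 0.48, Pcna 0.20, Igf1 0.36, Cd79b -0.20 and Fabp4 0.81, and the medians of lipid droplet, immediate early, periportal and B cell lists were 0.44, -0.19, 0.0748 and -0.20. With GC and length correction Aldh2 was at -0.19, Tiparp 0.0215, Gclm 0.42, Klf6 0.38, Pcna 0.31, Rgn 0.0732, Igf1 0.29, Cd79b -0.0654, Sox9 -0.0321, Fabp4 1.10 and mt-Nd6 0.20, and the medians of lipid droplet, immediate early, pericentral, periportal, B cell and mitochondrially encoded lists were 0.38, -0.0390, 0.0115, 0.17, -0.0654 and 0.14. On leaving out each library in turn Sox9 ranged from -0.33 to 0.23 and Jchain from -0.11 to 0.29, and the list medians from -0.32 to 0.42 for immediate early genes, -0.13 to 0.13 for p53 targets, -0.23 to 0.15 for pericentral markers, -0.11 to 0.16 for B cell markers, -0.23 to 0.34 for CAR and PXR targets and -0.0477 to 0.46 for the cell cycle. Without a change of sign, limma-voom moved Saa1 to 6.76, Saa2 to 7.71, Cyp1a1 to -7.80, Mup7 to -6.94, Mup12 to -7.27 and Cyp2c55 to -6.06. GC correction moved Rgn to -0.0158 and Jchain to 1.65, and GC and length correction Jchain to 1.79, Mup20 to -3.23, Mup14 to -3.46, Mup17 to -3.31, Mup8 to -4.62, Mup12 to -4.54, Cyp2c55 to -4.07, Cyp2c29 to -0.18, Slco1b2 to -1.0, Cyp7b1 to -1.35, Ifit1 to -2.28, Hsp90b1 to -1.34, Hsp90aa1 to -3.49, Per1 to 5.30, Clock to -1.45, S100a9 to 4.63, Gzma to 2.43, Spp1 to -0.63, mt-Nd4 to -0.52, Mlxipl to -1.59, Fabp1 to -1.40, Plin4 to 3.45 and Pcx to 1.01. RLE size factors moved the median of all genes by -0.0062 and GC correction by -0.0845 log2 units. No paired analysis was possible because the columns do not carry the replicate numbers of the labels, and no pseudocount alternative was run because counts were tested. Depth limits genes of few counts most, such as the granule enzymes and Ciart.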

Other observations

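The gene lists here were fixed before their values were seen, and the GC-corrected values and the counts of list members with a library left out come from tests chosen after the results were seen. Of all tested genes 66.4% passed, and 51.9% after GC correction. Counts of members near or below those shares do not set a list apart from other genes. In one-carbon metabolism 7 of 18 genes rose and 2 fell (8 when adjusted over the list alone, camera adjusted p = 0.235), or 6 and 2 after GC correction, with Mat1a, which makes S-adenosylmethionine, at 2.21 ± 0.23. Of 16 glucose metabolism genes 7 rose and 1 fell (8 over the list alone, adjusted p = 0.105), or 8 and 2 after GC correction, with pyruvate carboxylase Pcx at 1.69 ± 0.13 (1.11 after GC correction and 1.01 with GC and length correction). Of 12 iron handling genes 6 rose and 2 fell (8 over the list alone, adjusted p = 0.250), or 6 and 3 after GC correction, with the iron regulatory hormone Hamp at 1.40 ± 0.28. Of 14 lipid droplet and uptake genes 6 rose and 7 fell (13 over the list alone, adjusted p = 0.449), or 7 and 4 after GC correction, with the droplet coat protein Plin4 at 4.04 ± 0.49 (3.45 with GC and length correction). Fatty acid oxidation had 9 higher and 5 lower genes of 28 (12 over the list alone, adjusted p = 0.521), or 9 and 3 after GC correction, with the mitochondrial importer Cpt1a at 0.83 ± 0.16 and the fatty acid carrier Fabp1 at -2.29 ± 0.28 (-1.78 after GC correction and -1.40 with GC and length correction). Of 19 bile acid genes 2 rose and 8 fell (10 over the list alone, adjusted p = 0.368), but 5 rose and 7 fell after GC correction, with the uptake transporter Slco1b2 at -2.62 ± 0.16 (-0.92 ± 0.11 after GC correction). Leaving out A8 gave 9 lower fatty acid oxidation genes and 2 lower glucose genes. Lower glucose genes were also 2 without A4 and 3 without A6, and lower iron genes 1 without NC4. Lower one-carbon genes were 0 without A4, A7 or NC5 and 1 without A5, NC3 or NC4.

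Interferon response genes went both ways, 9 higher and 10 lower of 24 (20 over the list alone, camera adjusted p = 0.933), or 10 and 7 after GC correction, with Ifit1 at -3.16 ± 0.20 (-2.25 ± 0.19 after GC correction) and the transcription factor Irf7 at 1.06 ± 0.14. The unfolded protein and integrated stress list had 8 higher and 3 lower of 21 (11 over the list alone, adjusted p = 0.422), the same counts after GC correction and 5 lower without A5 or A8. Chac1 of this list, which degrades glutathione, was at 3.0 ± 0.27 and the chaperone Hsp90b1 at -2.10 ± 0.19 (-1.29 ± 0.16 after GC correction). The clock list had 6 higher and 4 lower of 19 (9 over the list alone, adjusted p = 0.449), or 6 and 2 after GC correction, and 3 higher without NC4, with Clock at -2.76 ± 0.17 (-1.46 ± 0.15 after GC correction). NRF2 and glutathione genes had 2 higher and 8 lower of 19 (10 over the list alone, adjusted p = 0.780), or 4 and 7 after GC correction, and 14 lower without A8. CAR and PXR targets had 6 higher and 7 lower of 20 (13 over the list alone, adjusted p = 0.933), or 6 and 4 after GC correction, and 3 higher without NC4 or NC5. Of 10 p53 targets 5 rose and 4 fell (10 over the list alone, adjusted p = 0.994), or 3 and 4 after GC correction, and 3 rose without NC4 or NC5. Stellate cell and fibrosis markers had 6 higher and 4 lower of 13 (10 over the list alone, adjusted p = 0.449), but 5 higher and 0 lower after GC correction. Pericentral markers had 4 higher and 5 lower of 13 (9 over the list alone, adjusted p = 0.933), or 5 and 4 after GC correction, and 2 higher without NC3 or NC4. Periportal markers had 6 higher and 6 lower of 16 (12 over the list alone, adjusted p = 0.948), or 4 and 5 after GC correction.

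Of 7 monocyte markers 4 rose (4 over the list alone, camera adjusted p = 0.208, 0.0467 after GC correction), and with an estimated correlation the adjusted p was 0.538, or 0.387 after GC correction. Fn1, Ly6c2, Itgam and Chil3 were these 4. Fn1 had 418712 counts after alcohol and 80018 after saline, far above Itgam (201 and 32) and Ly6c2 (155 and 12). Which cells its transcripts came from was not tested. The list had a median of 1.59, also with Chil3 at its bound, but of 0.89 without A4, 0.91 without A5 and 0.20 with genes under a mean of 50 counts left out. Chil3 had 57 counts after alcohol and 0 after saline, where 3 counts over the group are the floor, and so was at least 10.9-fold higher (6.80 without NC4, 7.21 without NC5). T and NK cell markers had 3 higher of 6 (3 over the list alone, adjusted p = 0.447), 2 after GC correction and 1 without NC4. None of the 3 held in every setting: Gzma lost its call without NC3 or NC4, Gzmb without NC4 or NC5 and with limma-voom, and Nkg7 without A4, A6, NC3 or NC5 and after GC correction (adjusted p = 0.114). Immediate early genes had 2 higher and 1 lower of 14 (0 over the list alone, adjusted p = 0.877), or 1 and 2 after GC correction. Without A4 they had 1 higher and 1 lower, without A6 or NC4 1 higher and 2 lower, and without A8 2 higher and 0 lower. Of 14 cell cycle genes 0 rose and 3 fell (0 over the list alone, adjusted p = 0.933), but 1 rose and 0 fell after GC correction, and 5 fell without A8 and 1 without NC5. Red blood cell genes had 1 lower of 5 (0 over the list alone, adjusted p = 0.910), which was lost without A4, A5, NC3, NC4 or NC5, and 2 higher without A6. Of 3 B cell markers 0 passed (0 over the list alone, adjusted p = 0.989), with 1 higher and 1 lower after GC correction and 1 lower without NC4. Lists with under 3 tested members were not tested as lists. Of the pancreas genes Cela1 was tested (-1.90 ± 0.39), of the adipose genes Fabp4 (-0.61 ± 0.17, or 0.81 ± 0.18 after GC correction), and of the muscle genes 0.

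Counts after GC correction also moved with a library left out. Lower genes without A8 were 13 for NRF2 and glutathione, 7 for fatty acid oxidation and 2 for the cell cycle, which had 1 lower without A7. Higher genes without NC4 were 3 for bile acids, 1 for p53 targets and 0 for immediate early genes, of which 5 fell there. Immediate early genes had 2 higher without A8 or NC3, and 1 lower without A4, A5, A6, A7 or A8. Lower glucose genes were 1 without A4, A5, A7, NC3 or NC5, lower one-carbon genes 1 without NC5, and lower clock genes 1 without A4, A5, A7 or NC4. The cell cycle gene that rose was lost without A4, A5, A7, NC3, NC4 or NC5. Stellate cell markers had 3 higher without NC5 and 1 lower without NC3, and B cell markers 0 lower without NC3.

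Alcohol library A6 held the highest level of Cyp2b13 (124.58 CPM, against 9.75 to 39.42 in the other 4 alcohol libraries), which is more highly expressed in female than in male mouse liver.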
